A study of Mus musculus with 139 samples.

How the data were processed

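Gene expression was measured by RNA sequencing in cortex and hippocampus of mice that carry a deletion modelling a human copy number variant at 15q13, 1q21 or 22q11. Per the labels, the series holds 139 libraries from 5 numbered sequencing studies. Each library is labelled with its model, tissue, genotype, sex and study number, and the labels name no batch, litter, age or dissection date. Single reads of 50 bp were labelled for 102 libraries and reads of 100 bp for the 37 libraries of study 1. Per the submitters' processing notes, libraries were made with a stranded poly(A) mRNA kit, reads were aligned to GRCm38 with STAR 2.5.2b, and reads per gene were counted with featureCounts 1.5.1. The notes do not say which strand setting was used in counting.

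The deposited values are raw counts per gene, as whole numbers, in 1 file per library. Among counts of 1 to 199, 41.5% to 44.2% were even in libraries with single reads, and 56.6% to 62.7% were even in study 1. The excess of even counts is what results when the authors count both mates of a read pair, so total counts of study 1 are not comparable with those of the other studies, and counting error there is understated by the raw count. An alternative with the counts of study 1 halved was therefore run. Genes were placed with the GENCODE M21 annotation of GRCm38, which gave chromosome, start, end and biotype by gene symbol. A check of sex-linked genes found 0 of 139 libraries that did not match their labelled sex. No 2 libraries of a group were duplicates: over 589 pairs within groups, the index of dispersion between their counts ran from 2.48 to 474.2, where 1 is sampling noise.

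Samples were compared only within a study, so that each group of mutants was set against the wild-type libraries sequenced with it. This gave 8 comparisons of mutant with wild type. In each, genes were kept by filterByExpr of edgeR 4.0.16 on the groups (minimum count 10, minimum total 15). Library sizes were scaled by TMM, and the quasi-likelihood test of edgeR was run with genotype as the term, and with sex as a second term in study 1, where both sexes were present. P values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene passed at an adjusted p of 0.05. The standard error (SE) of a log2 fold change was its size divided by the square root of the F statistic. Levels are given as CPM, the count a gene would have in a scaled library of 1000000 counts, as mean ± SD over libraries. Genes of the deleted interval were listed by name before the data were examined, were reported separately and were left out of the counts of changed genes. Differences between the effects in 2 comparisons were tested as an interaction in a joint edgeR fit with a mean per group, and with a sex term for the libraries of study 1.

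A total of 33 gene lists (pathways, protein complexes, and markers of cell types and of neighbouring brain regions) were fixed before the data were examined. Each was tested in each comparison with camera of limma 3.58.1 on voom values with a preset correlation between genes of 0.01, adjusted over the lists of that comparison. The same test with the correlation estimated from the residuals, and the rotation test fry, were run beside it. Members were also adjusted over the list alone. Of the 82 calls among 264 tests of lists, 1 was also made with an estimated correlation, namely that of the microRNA host transcripts in 22q11 hemizygous cortex. The score of a list in a library is the mean over its members of log2 CPM (prior count 2) minus the mean of the wild-type libraries.

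The genes named in the text were chosen by a rule fixed before the data were examined. The rule takes each deleted gene that was tested, the 5 largest rises and 5 largest falls among genes past the threshold with a mean of at least 1 CPM in either group, the 5 next smallest adjusted p, and for each list past its threshold the 3 members with the smallest p in its direction. Other genes were named after their values were seen, and not each of them is marked as such in the text. They are members of the microRNA host list such as Meg3, and genes inside an interval that were not on the deleted list. Unless the rule also took them, they also include genes named for a difference between comparisons, for a shared call or for the nuclear-retained covariate. Correlations between comparisons were taken across genes over mean log2 CPM differences, with p from reassigning genotypes within each comparison. Single values were compared by two-sided permutation tests, exact where a group held fewer than 10 libraries and otherwise with 100000 draws.

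For genes at 0 counts in the mutants, the bound on the fold used a floor of 3 counts over the whole group, and 95% intervals of percentages are exact Poisson intervals of the mutant count. These cover at most counting error, since reads without molecular identifiers are not independent molecules. The intervals took the counts of study 1 as deposited, where both mates appear to have been counted, so they are too narrow if that is so. The calling was tested on simulated data. For each comparison, counts were drawn with the dispersions of its libraries and 200 genes were changed by a known fold, and 2.03% to 15.8% of the calls were false. Of genes raised or lowered 1.25-fold, 60.5% were called with the design of the 15q13 hemizygous cortex. None (0%) were with that of the 15q13 hemizygous hippocampus, where 3 libraries stood against 3. Each gene was drawn independently, so shifts shared by many genes within a library were not simulated. Another split of the real 15q13 homozygous cortex libraries called 1784 genes, so the simulated shares may not hold for the real data.

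The alternatives were DESeq2 1.42.0 size factors, the DESeq2 Wald test, no filter on low counts, 2 surrogate variables of sva 3.50.0, sample quality weights in limma, a joint fit with the other model of the same study, no sex term, females alone, and leaving out each library in turn where a group had 3 to 5. Those chosen after seeing the data were the removal of the interval by coordinates, halved counts, a covariate built from 18 nuclear-retained transcripts, and the removal of libraries that stood apart. The counts of changed genes, of lists past the threshold and of genes with a different effect were also recomputed on up to 100 splits of the same libraries, the real one included. Nothing deposited was left out. Scripts ran in R 4.3.3 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.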

Results

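RNA sequencing measured gene expression in cortex and hippocampus of mice with deletions that model the human 15q13, 1q21 and 22q11 copy number variants. The mouse intervals, taken between the outermost deleted genes on GRCm38, were chromosome 7 from 63098692 to 64374095 for 15q13 (1.28 Mb), chromosome 3 from 96868281 to 97673812 for 1q21 (0.81 Mb) and chromosome 16 from 17839482 to 18970309 for 22q11 (1.13 Mb). Hemizygous mice lack 1 copy of the interval and homozygous mice lack both. For 15q13, cortex was compared in 10 hemizygous and 10 wild-type mice and in 8 homozygous and 11 wild-type mice, and hippocampus in 3 hemizygous and 3 wild-type mice and in 8 homozygous and 10 wild-type mice. For 1q21, the groups were 12 hemizygous and 5 wild-type cortices and 10 hippocampi of each genotype. For 22q11, they were 10 cortices of each genotype, 9 hemizygous hippocampi and 10 wild-type hippocampi. Libraries with single reads came from males, and the homozygous study held both sexes. Total counts per library ran from 8.05 to 23.93 M, where 1 M stands for 1000000 counts, in the 102 libraries with single reads. In the homozygous study, in which both mates appear to have been counted, they ran from 45.58 to 223.6 M. Each comparison asks which genes, inside and outside the deleted interval, differed in level between mutants and their wild-type controls.

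In 22q11 hemizygous cortex, all 24 deleted genes that could be tested fell, to a median of 49.5% of wild type (median log2 fold change -1.01, n = 10 and 10). They include the septin Sept5 (log2 fold change -1.05 ± 0.04 SE) and the endothelial tight junction gene Cldn5 (-0.99 ± 0.13). Dgcr8, which encodes the RNA-binding partner of Drosha in the cleavage of primary microRNAs, was lowered least: it kept 73.4% of the wild-type level (-0.45 ± 0.08, lower in 10 of 10 mutants). Trmt2a, a tRNA methyltransferase, kept 60.3% (-0.73 ± 0.08), and the catenin Arvcf 58.6% (-0.77 ± 0.06). Ess2 and the palmitoyltransferase Zdhhc8 each changed by -0.83. Within 1 Mb of the interval, 0 of 29 genes fell in the edgeR test and 4 rose: Top3b (0.28), Tmem191c (0.34), Aifm3 (0.60) and Smpd4 (0.73), which were named after their values were seen. Across the genome 1011 of 14506 genes rose, and in hippocampus 0 of 30 genes within 1 Mb changed, so a local effect of the deletion is not shown.

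**Figure D1:**
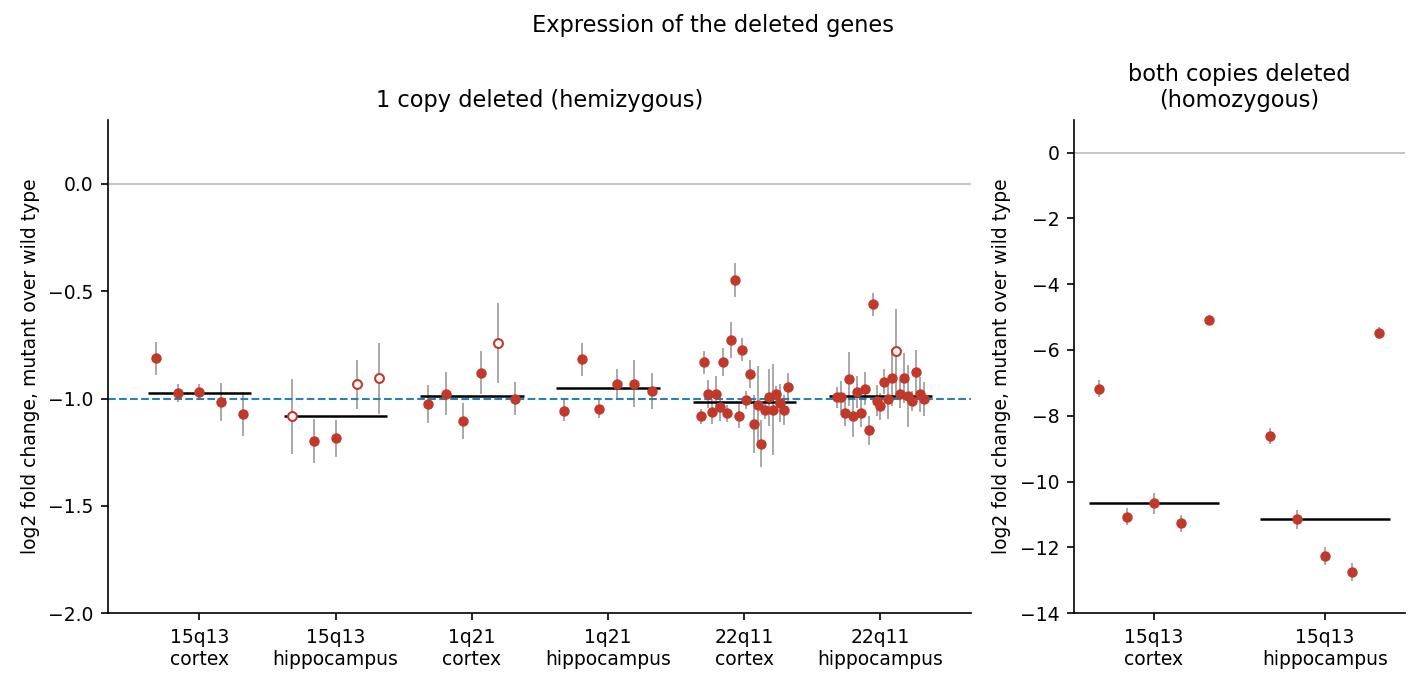
Log2 fold change of each deleted gene, mutant over wild type, with its standard error, for the 6 hemizygous comparisons (left) and the 2 homozygous comparisons (right). Filled points passed an adjusted p of 0.05, black lines are medians, and the dashed line marks a halved level; hemizygous medians lie between -1.08 and -0.95, homozygous medians at -10.66 and -11.14.

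Long non-coding transcripts that contain microRNAs were among the genes with the largest rises or the smallest p outside the interval in 22q11 hemizygous cortex. Of all 1381 genes changed outside the deleted list, 119 were annotated microRNA hosts or microRNAs, as were 748 of 14471 genes tested (5.17%). A330023F24Rik rose 4.79-fold, to 62.9 ± 22.4 CPM (mean ± SD; log2 fold change 2.26 ± 0.18, adjusted p = 5.9e-09, edgeR), above every wild-type library in 10 of 10 mutants. Mirg rose by 2.00 ± 0.18, E130102H24Rik by 1.37 ± 0.13, 4833445I07Rik by 0.78 ± 0.08, C130071C03Rik by 0.60 ± 0.05 and Mir9-3hg by 0.50 ± 0.06. Emc10, a subunit of the endoplasmic reticulum membrane complex, rose from 206 ± 9.08 to 292 ± 13.4 CPM (0.51 ± 0.03, adjusted p = 2.3e-10), the smallest p outside the interval, and lay above every wild-type library in 10 of 10 mutants. Further large rises were those of 9530059O14Rik (2.15 ± 0.24), the zinc transporter Slc39a2 (1.95 ± 0.27) and Gm37795 (1.83 ± 0.23). Of the fixed list of microRNA host transcripts, 8 of 10 measured members rose over all genes tested and 9 adjusted over the list alone. Emc10 is on the list and among these but hosts no annotated microRNA. The others included Meg3 (1.49 ± 0.23), Mir124a-1hg (1.54 ± 0.19) and Mir22hg (0.47 ± 0.06), which were named after their values were seen. The list passed the camera test (adjusted p = 8.9e-13) and also with an estimated correlation (adjusted p = 0.000271).

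In 22q11 hemizygous cortex, 6 lists of metabolism, protein folding and protein turnover passed the camera test downward, but each lost its call with an estimated correlation (adjusted p = 0.844 for 5 of them and 0.974 for the cytosolic ribosomal proteins). Of 74 nuclear-encoded subunits of oxidative phosphorylation, 14 fell and 0 rose (32 fell and 1 rose adjusted over the list alone), among them the complex III subunits Uqcrfs1 (-0.17 ± 0.03) and Uqcrq (-0.17 ± 0.04) and the complex I subunit Ndufb9 (-0.22 ± 0.06). All 15 genes of the unfolded protein response were lower and 3 fell (9 adjusted over the list alone): Xbp1 (-0.19 ± 0.05), Dnajb9 (-0.17 ± 0.05) and the chaperone Hspa5 (-0.24 ± 0.07). Of 31 proteasome genes 1 fell, Psmb6 (-0.12 ± 0.03; 9 fell adjusted over the list alone), of 75 mitochondrial ribosomal proteins 3 fell, of 79 cytosolic ribosomal proteins 4 fell and 1 rose, and of 21 genes of cholesterol synthesis 1 fell, Msmo1 (-0.26 ± 0.08). Mural and meningeal markers were higher in 14 of 16 with 0 past the threshold, and that list too lost its call (adjusted p = 0.974 with an estimated correlation). The largest falls among single genes were those of Tmem160 (-0.51 ± 0.09), Aldh1a3, which makes retinoic acid (-0.50 ± 0.16), Metrnl (-0.50 ± 0.11), Rab5if (-0.46 ± 0.10) and Gm37194 (-0.59 ± 0.18).

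Outside the deleted list, 1381 of 14506 genes changed in 22q11 hemizygous cortex, of which 1011 (73.2%) rose and 370 fell (edgeR, adjusted p under 0.05), and DESeq2 called 1736. Mutant libraries also held more of 18 transcripts known to be retained in the nucleus, a list chosen by hand after the calls were seen: 15 of the 18 rose, and their mean was 0.51 log2 higher than in wild type (permutation test, two-sided, adjusted p = 0.00152 over 8 comparisons). Because the list followed the cortex calls, this p is not an independent test in cortex. In 22q11 hippocampus the same mean was lower in mutants by 0.26, with 0 of the 18 transcripts higher (adjusted p = 0.0108). With that mean as a covariate, 13 genes outside the interval rose and 0 fell, among them Emc10 (0.58 ± 0.05), A330023F24Rik (1.43 ± 0.13) and C130071C03Rik (0.58 ± 0.07). Mirg was then 1.14 ± 0.09 and Mir124a-1hg 0.57 ± 0.11, and the median over 42 annotated long non-coding hosts went from 0.51 to 0.20. The covariate differs between the genotypes, so it removes part of any effect of the deletion.

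**Figure D2:**
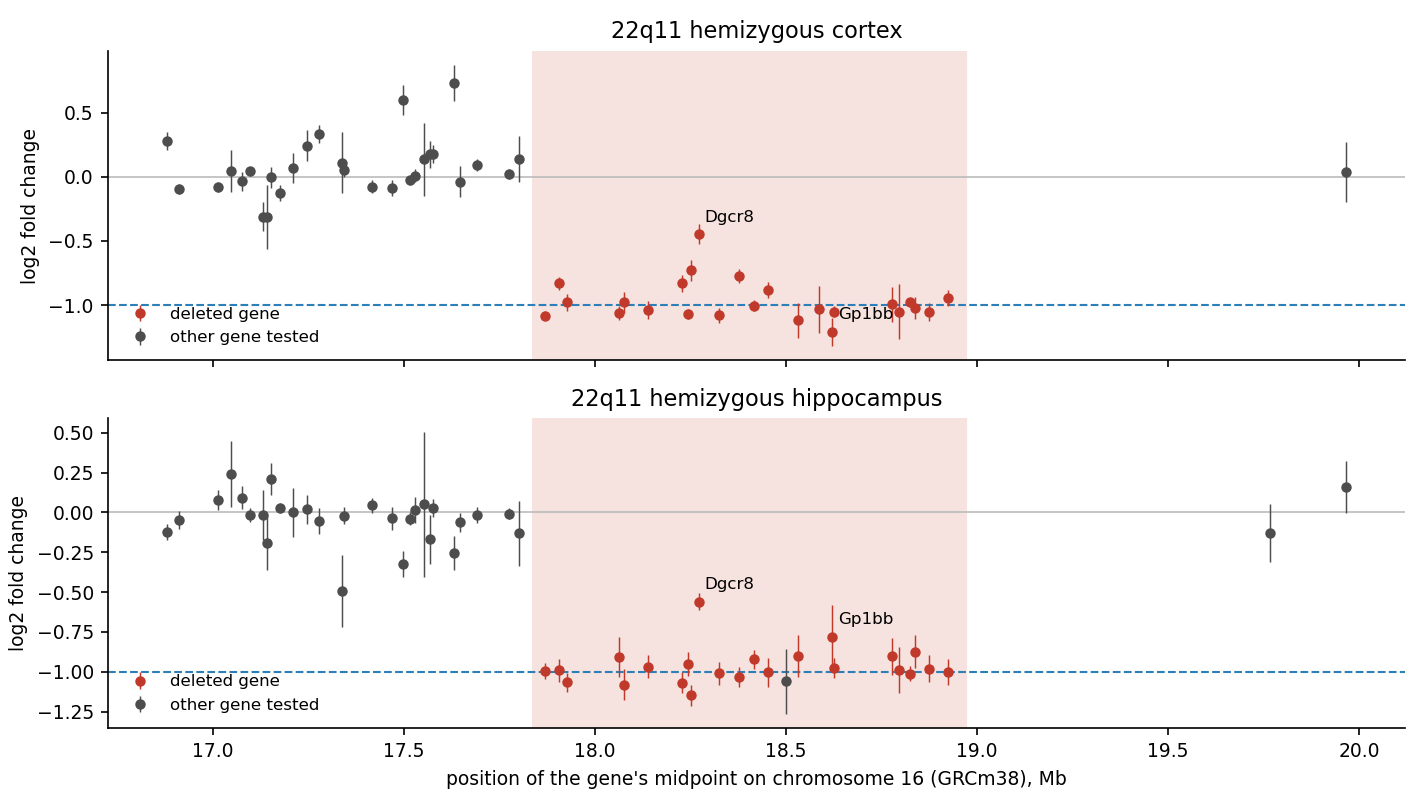
Log2 fold change (mutant over wild type, with standard error) of genes on chromosome 16 against the position of the gene's midpoint in Mb, in cortex (top) and hippocampus (bottom). The shaded span is the 22q11 interval of 1.13 Mb, the dashed line marks a halved level, and Dgcr8 lies above the other deleted genes at -0.45 and -0.56.

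In 22q11 hemizygous hippocampus, 22 of 23 deleted genes fell, to a median of 50.7% of wild type (log2 -0.99, n = 9 and 10). The exception was the platelet glycoprotein gene Gp1bb (-0.78 ± 0.20, adjusted p = 0.139), which passed adjusted over the list alone. Dgcr8 kept 67.8% (-0.56 ± 0.05, lower in 9 of 9 mutants). Emc10 again rose, from 148 ± 12.8 to 222 ± 14.6 CPM (0.59 ± 0.05, adjusted p = 8.5e-08), and all 9 mutants lay above the wild-type libraries for Emc10 and for C130071C03Rik (0.50 ± 0.05).

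Outside the deleted list, 15 of 14908 genes changed in 22q11 hemizygous hippocampus, 8 up and 7 down (edgeR; DESeq2 called 62). Besides Emc10 and C130071C03Rik, the rises were those of the microRNA hosts Mir22hg (0.46 ± 0.07), 4833445I07Rik (0.49 ± 0.10), 2010111I01Rik (0.40 ± 0.08) and 5330434G04Rik (0.39 ± 0.08), the microRNA gene Mirlet7c-2 (1.24 ± 0.23) and Rnf17, known from germ cells (from 0.609 ± 0.261 to 1.48 ± 0.394 CPM). The falls were those of Dnmt3a, a de novo DNA methyltransferase (-0.25 ± 0.05), Atrip, which acts in the DNA damage checkpoint (-1.07 ± 0.21), Krba1 (-0.36 ± 0.07), Yeats2 (-0.22 ± 0.05), Gm15328 (-0.82 ± 0.18), Gm43481 (-0.64 ± 0.12) and Rtl10 (-1.06 ± 0.20), which lies inside the deleted interval at 18498901 but was not on the list of deleted genes. All 7 measured mitochondrially encoded mRNAs were higher, with 0 past the threshold and 3 adjusted over the list alone, such as mt-Cytb (0.27 ± 0.08). Inhibitory neuron markers were higher in 10 of 14, for example Sst (0.24 ± 0.10) and Slc32a1 (0.18 ± 0.07), with 0 past either threshold, and cholinergic signalling genes in 11 of 16. Each of these 3 lists passed camera and lost its call with an estimated correlation (adjusted p = 0.415). So did 6 more with 0 genes past either threshold: subunits of oxidative phosphorylation (higher in 55 of 72, such as Cox8a, 0.27 ± 0.11), mitochondrial ribosomal proteins (58 of 75), synaptic vesicle genes (18 of 25) and markers of the CA fields (7 of 9) were higher, and genes of cholesterol synthesis (19 of 21) and immediate-early genes (15 of 18, such as Fosb, -0.58 ± 0.22) lower (adjusted p = 0.729 for the CA fields and 0.924 for the others). Whether lists differ between the tissues was not tested. Striatal markers, which did not pass (adjusted p = 0.0543), scored 2.04 in hemizygous library 123 and at most 0.31 in the 17 libraries kept when it and wild-type library 113 were left out; 27 genes changed without these libraries.

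**Figure D3:**
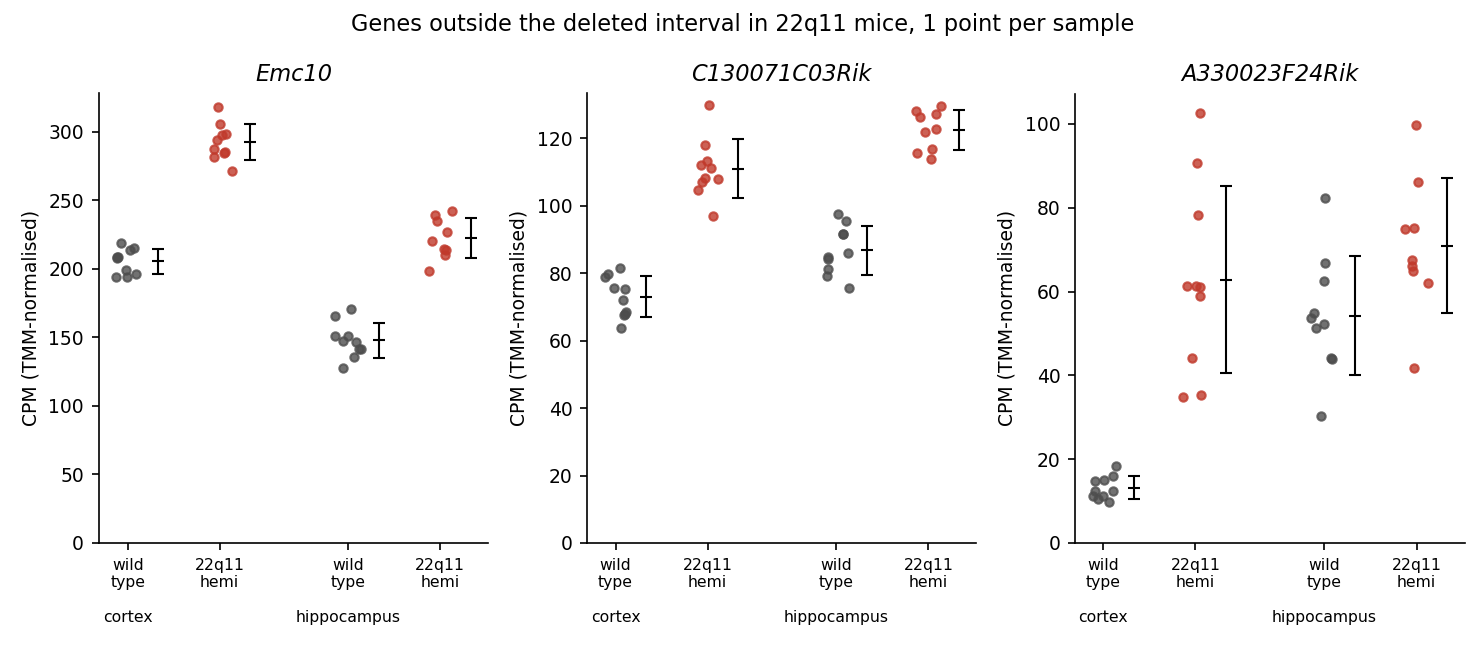
CPM per library of Emc10, C130071C03Rik and A330023F24Rik in wild-type and 22q11 hemizygous cortex and hippocampus; each point is a library, and the bar and whiskers are mean and SD. For Emc10 and C130071C03Rik the 10 cortex and 9 hippocampus mutants lie above their wild-type controls.

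The effects of the 22q11 deletion differed between the tissues for 1476 genes outside the deleted list (interaction test in edgeR), 1090 of them higher in cortex. A330023F24Rik rose by 2.26 in cortex and was 0.39 higher in hippocampus, a difference of 1.85 ± 0.24 (adjusted p = 3.6e-05); with the nuclear-retained mean as covariate it rose in both, by 1.43 ± 0.13 and 0.95 ± 0.09. Slc39a2 (difference 2.42 ± 0.34), the microRNA host Mir124a-1hg (1.80 ± 0.26) and the kinesin-like Stard9 (0.88 ± 0.12) also differed. Of the deleted genes, Trmt2a (difference 0.41, adjusted p = 0.0114) and Arvcf (0.25, adjusted p = 0.0491) were lowered less in cortex. Of the genes that rose in either tissue, 6 were shared, against 0.417 if the calls were independent. Tissue and sequencing study cannot be separated, since cortex and hippocampus came from different studies, and the nuclear-retained mean moved in opposite directions in the 2 tissues (0.51 and -0.26).

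In 1q21 hemizygous cortex, the deleted genes fell to a median of 50.3% of wild type (log2 -0.99, n = 12 and 5). They were Prkab2, a regulatory subunit of the energy sensor AMPK (from 67.2 ± 5.32 to 33.6 ± 4.06 CPM), Bcl9, a coactivator of Wnt signalling (-1.11 ± 0.08), the acid phosphatase Acp6 (-0.98 ± 0.10), Gpr89 (-1.02 ± 0.09) and the chromatin remodeller Chd1l (-0.88 ± 0.10). Fmo5, a flavin monooxygenase at 3.84 CPM in wild type, was -0.74 ± 0.19 lower and did not pass over all genes (adjusted p = 0.928), although it did adjusted over the list alone.

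Outside the interval, 0 of 14905 genes changed in 1q21 hemizygous cortex in the edgeR test, while 739 had an unadjusted p under 0.05 and DESeq2 called 1. Among the lists, 66 of 76 cytosolic ribosomal proteins and 55 of 74 subunits of oxidative phosphorylation were higher, with 0 past either threshold and medians of 0.11 and 0.07. Synaptic vesicle genes were lower in 24 of 25 (median -0.09), excitatory neuron markers in 11 of 12 (-0.13) and genes of cholesterol synthesis in 18 of 21 (-0.09), also with 0 past either threshold. Immediate-early genes, which respond to neuronal activity, were higher in 16 of 18 (median 0.35), such as Nr4a3 (0.75 ± 0.36). All 11 striatal markers were higher (median 1.75), for instance the adenosine receptor gene Adora2a (2.95 ± 1.34), and this rested on hemizygous libraries 15 and 16, which scored 4.75 and 1.10 for striatum against at most 0.38 in the other 15. These libraries also scored highest for choroid plexus markers (3.33 and 1.57). Also with 0 past either threshold, genes of glycolysis and the TCA cycle (28 of 34) and of the postsynaptic density (26 of 34) were lower, and mitochondrial ribosomal proteins (51 of 75), the unfolded protein response (13 of 15), microglial (11 of 12) and mural and meningeal markers (15 of 16) higher. In all, 13 lists passed camera and 0 did with an estimated correlation (adjusted p of at least 0.684); without libraries 15 and 16, 8 passed.

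In 1q21 hemizygous hippocampus, all 6 deleted genes fell, to a median of 51.6% of wild type (log2 -0.95, n = 10 and 10), from Bcl9 (-1.05 ± 0.04) and Gpr89 (-1.06 ± 0.05) to Acp6 (-0.82 ± 0.08). Some genes of mitochondrial proteins rose outside the interval: the mitochondrial ribosomal protein gene Mrpl34 from 12.7 ± 1.36 to 16.9 ± 2.23 CPM (0.42 ± 0.08, adjusted p = 0.0286, higher in 9 of 10 mutants), Fmc1, an assembly factor of ATP synthase (0.42 ± 0.08), and Cox14, an assembly factor of cytochrome oxidase (0.36 ± 0.07). Olig1, an oligodendrocyte transcription factor (0.36 ± 0.07), Edf1 (0.30 ± 0.06), Akt1s1, an inhibitor of mTORC1 (0.27 ± 0.05), Ngrn (0.23 ± 0.04) and Ogfod2 (0.22 ± 0.04) rose as well. The falls were those of the long non-coding Gm26723 (-1.58 ± 0.29, lower in 10 of 10 mutants) and Gm14703 (-1.02 ± 0.21), and of Pter (-0.74 ± 0.15), Nme7 (-0.31 ± 0.06), the RNA-binding Syncrip (-0.16 ± 0.03) and the splicing helicase Ddx46 (-0.13 ± 0.03).

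These 14 of 14839 genes (8 up, 6 down) were the changes outside the interval in 1q21 hemizygous hippocampus, and DESeq2 called 95. Of 75 mitochondrial ribosomal proteins 1 rose (11 adjusted over the list alone) and 56 were higher; of 72 subunits of oxidative phosphorylation 0 rose (9 adjusted over the list alone), with Cox8a at 0.55 ± 0.13. All 15 genes of the unfolded protein response were higher (0 past the threshold, 4 adjusted over the list alone), such as Sdf2l1 (0.62 ± 0.19) and the calcium-binding chaperone Calr (0.19 ± 0.06). The first and last of these lists had an adjusted p of 0.508 with an estimated correlation and the second of 0.633, so that none kept its call. Thalamic and habenular markers were higher in 10 of 10 (median 0.76; 6 adjusted over the list alone; adjusted p = 0.633 with an estimated correlation), such as Tcf7l2 (1.10 ± 0.35), and hemizygous libraries 95, 96 and 99 scored 1.34, 1.48 and 1.86 against at most 0.56 in the other 17. Lists of mitochondrially encoded mRNAs (7 of 7) and cholesterol synthesis (15 of 21) passed downward (adjusted p = 0.633 and 0.706 with an estimated correlation). Without hemizygous libraries 95, 96 and 99, 2 genes changed, of which 1 was among the 14. Fewer mutants also mean fewer calls, so a lost call alone does not show that these libraries carried the change. Between cortex and hippocampus, the effect of the 1q21 deletion differed for 0 genes in edgeR and for 30 in DESeq2.

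In 15q13 homozygous cortex, transcripts of the deleted genes were close to absent, with median log2 -10.66 (n = 8 and 11). Of the summed counts per library total, Chrna7, the alpha7 nicotinic acetylcholine receptor subunit, kept 0.661% (95% interval 0.442% to 0.949%), Klf13 0.0628%, the deubiquitinase Otud7a 0.0417% and the phosphatase-like Mtmr10 0.0325%. Fan1, a nuclease of DNA crosslink repair, kept 2.89%. Trpm1, which did not pass the filter, had 0 counts in mutants and 132 in wild type, so that it was at least 30.3-fold lower (15.4-fold with counts halved, as both mates appear to have been counted), and the antisense transcript Gm20457 was at least 460-fold lower (231-fold with counts halved). The non-coding Gm44741, Gm44718, Gm27252 and Gm32633 inside the interval also had 0 counts in mutants. In contrast, the processed pseudogene Gm5898 inside the interval kept 30.2%. Within 1 Mb of the interval, 0 of 11 genes changed.

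Outside the deletion, a few low transcripts rose in 15q13 homozygous cortex, and single genes of inhibitory neurons and of the response to activity fell. Cyp2e1, a cytochrome P450 known from liver, rose from 0.236 ± 0.139 to 1.31 ± 0.481 CPM (5.65-fold, adjusted p = 0.00021, above all wild types in 8 of 8 mutants), and the long non-coding Gm28322 rose by 2.35 ± 0.36. Fchsd1, an actin-binding F-BAR protein gene, rose from 8.08 ± 1.34 to 12.9 ± 1.54 CPM (0.67 ± 0.09, above all wild types in 8 of 8). The interferon-inducible Ifi27l2a (1.08 ± 0.21), Ifi203 (1.07 ± 0.18) and Mndal (0.85 ± 0.13) rose too. All 14 measured markers of inhibitory neurons were lower and 2 fell (6 adjusted over the list alone): Gad1, which synthesises GABA, from 353 ± 30.4 to 263 ± 32.0 CPM (-0.42 ± 0.07, lower in 8 of 8) and the vesicular GABA transporter Slc32a1 (-0.37 ± 0.07). Pvalb was -0.59 ± 0.16 and did not pass over all genes. That list had an adjusted p of 0.0902 with an estimated correlation and 0.00469 with fry. All 18 immediate-early genes were lower and 1 fell (11 adjusted over the list alone), Dusp1, a MAP kinase phosphatase (-1.06 ± 0.21); Arc stood at -1.29 ± 0.29 (adjusted p = 0.0703), and the list had an adjusted p of 0.430 with an estimated correlation. Csrnp1 (-0.75 ± 0.12), Arl4d (-0.74 ± 0.12) and the orphan receptor gene Gpr3 (-0.73 ± 0.15) fell as well.

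Metabolic and other lists passed the camera test in 15q13 homozygous cortex, but 0 of 12 kept their call with an estimated correlation. All 74 subunits of oxidative phosphorylation were lower, with 0 past the threshold over all genes and 41 adjusted over the list alone (median -0.20), for example Cox5a (-0.33 ± 0.09). Of 34 genes of glycolysis and the TCA cycle 33 were lower (20 adjusted over the list alone), such as Mdh2 (-0.29 ± 0.07), and of 21 genes of cholesterol synthesis 20 (4 adjusted over the list alone). The 31 proteasome genes, of which 30 were lower, and the cytosolic and mitochondrial ribosomal proteins had medians of -0.13 with 0 past either threshold. Synaptic vesicle genes were lower in 19 of 25 (3 adjusted over the list alone) and GABA-A receptor subunits in 9 of 12, while interferon-responsive genes were higher in 14 of 15 and mural and meningeal markers in 14 of 16. With an estimated correlation the adjusted p was 0.430 for oxidative phosphorylation, glycolysis and the mitochondrial ribosome, 0.444 for cholesterol synthesis, 0.445 for the proteasome, 0.485 for the interferon-responsive genes, 0.751 for the GABA-A receptor subunits and 0.761 for the other three.

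Outside the deleted list, 46 of 19534 genes changed in 15q13 homozygous cortex, 17 up and 29 down, of which 6 falls lay inside the interval by coordinates (edgeR; 2429 had an unadjusted p under 0.05 and DESeq2 called 251). Among females alone 19 genes changed, and 211 did with surrogate variables.

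In 15q13 homozygous hippocampus, the deleted genes had a median log2 of -11.14 (n = 8 and 10). Chrna7 kept 0.250% of wild type, Fan1 2.07%, Klf13 0.0195%, Otud7a 0.0407% and Mtmr10, with 2 counts, 0.00898% (95% interval 0.00109% to 0.0324%). That interval treats the 2 counts as separate reads, though they may be mates of the same pair. Trpm1 was at least 34.8-fold lower and Gm20457 at least 824-fold lower (17.96-fold and 413-fold with counts halved), while Gm5898 kept 40.5%. Cyp2e1 rose from 0.177 ± 0.0746 to 1.18 ± 0.672 CPM (2.79 ± 0.24, adjusted p = 1.1e-06, above all wild types in 7 of 8 mutants), Gm28322 by 1.91 ± 0.15 and Fchsd1 by 0.77 ± 0.08. Otof, which acts in vesicle release of inner hair cells (1.90 ± 0.33), the methyltransferase-like Mettl24 (1.46 ± 0.30), the iodide transporter Slc5a5 (0.98 ± 0.20) and the copine Cpne5 (0.79 ± 0.07, above all wild types in 8 of 8) also rose. The falls included the calcium-binding Casq2 (-0.97 ± 0.16), the p53 target Pmaip1 (-0.83 ± 0.14), the potassium channel subunit Kcnab3 (-0.73 ± 0.12) and Dmp1 (-0.63 ± 0.13).

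Outside the deleted list, 50 of 19975 genes changed in 15q13 homozygous hippocampus, 35 up and 15 down, of which 5 falls lay inside the interval (edgeR; DESeq2 called 259). Immediate-early genes were lower in 13 of 18 with 0 past the threshold (11 adjusted over the list alone), such as Nr4a1 (-0.95 ± 0.25) and Junb (-0.68 ± 0.19). Hemoglobin and other erythrocyte genes were higher in 6 of 6 (5 adjusted over the list alone), for instance Hbb-bs (0.67 ± 0.19), mural and meningeal markers in 13 of 16, such as Dcn (1.69 ± 0.43), and interferon-responsive genes in 14 of 15, such as Usp18 (1.03 ± 0.30). Genes of the unfolded protein response were higher in 14 of 16 and endothelial markers lower in 8 of 12 (4 adjusted over the list alone), such as Tek (-0.41 ± 0.10). These 6 lists had an adjusted p of 0.709 with an estimated correlation and so lost their calls, as did cytosolic ribosomal proteins (75 of 79 lower), myelin genes (12 of 12 lower), glycolysis and the TCA cycle (27 of 34 higher), synaptic vesicle genes (21 of 25 higher) and thalamic markers (9 of 10 lower), at 0.709 or above. Wild-type library 236 scored 1.33 for thalamus where the next wild type scored 0.25. For interferon-responsive genes, homozygous library 241 scored 0.996 where the next scored 0.29, and wild-type library 248 scored -0.29 where the next scored -0.09. Choroid plexus markers, whose list did not pass (adjusted p = 0.814), scored 4.02 in homozygous library 249 and at most 2.66 in the other 17. Library 249 also scored 0.996 for striatum and 0.35 for oxidative phosphorylation, against at most 0.28 and 0.19 in the other 17.

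Cortex and hippocampus of 15q13 homozygotes shared 8 changed genes outside the interval, with the same sign in both: Cyp2e1, Gm28322, Gm32122, Fchsd1, the liver glycogen phosphorylase Pygl, Cand2 and Armcx6 rose and Gm42500 fell. Pygl rose by 0.76 ± 0.14 in cortex and 0.93 ± 0.15 in hippocampus, and Armcx6 by 0.52 ± 0.09 and 0.76 ± 0.09. In the interaction test 0 genes differed in effect between the tissues by edgeR (1369 at an unadjusted p under 0.05) and 0 by DESeq2. The labels do not say whether both tissues came from the same animals.

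**Figure D4:**
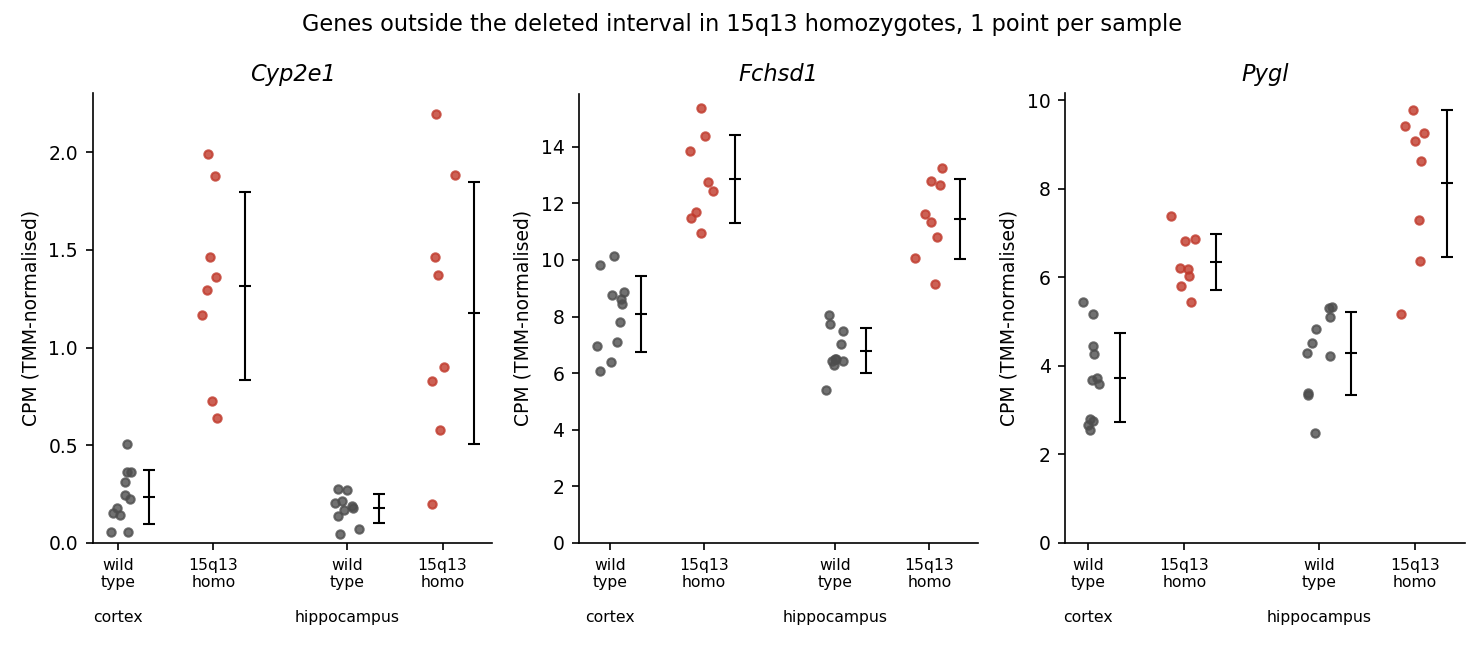
CPM per library of Cyp2e1, Fchsd1 and Pygl in wild-type and 15q13 homozygous cortex and hippocampus; each point is a library, and the bar and whiskers are mean and SD. All 8 homozygotes lie above the wild-type libraries for Fchsd1 in each tissue.

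In 15q13 hemizygous cortex, the 5 deleted genes that could be tested fell to a median of 50.9% of wild type (log2 -0.97, n = 10 and 10): Klf13 (-0.97 ± 0.04), Otud7a (-0.97 ± 0.04), Mtmr10 (-1.02 ± 0.09), Fan1 (-1.07 ± 0.10) and Chrna7, which kept 56.8% (-0.81 ± 0.08). Markers of oligodendrocytes and myelin were lower in 12 of 12 (median -0.21), such as Mobp (-0.31 ± 0.17), and astrocyte markers in 10 of 12 (-0.07), such as the bicarbonate transporter Slc4a4 (-0.15 ± 0.05). Erythrocyte genes were higher in 5 of 5 (0.32), such as Alas2 (0.34 ± 0.16). In each of these 3 lists 0 genes passed over all genes or adjusted over the list alone. The lists passed camera and lost their calls with an estimated correlation (adjusted p = 0.532 for myelin and erythrocytes and 0.817 for astrocytes). Outside the interval 0 of 14419 genes changed in edgeR, with 454 at an unadjusted p under 0.05 and 2 called by DESeq2.

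In 15q13 hemizygous hippocampus, with 3 mutants and 3 wild types, the deleted genes had a median of 47.2% of wild type (log2 -1.08). Otud7a (-1.20 ± 0.10, adjusted p = 0.0168) and Klf13 (-1.18 ± 0.09, adjusted p = 0.0112) fell; Chrna7 (-1.08 ± 0.17), Mtmr10 (-0.93 ± 0.11) and Fan1 (-0.91 ± 0.17) passed only adjusted over the list alone. Thalamic and habenular markers were higher in 10 of 10 (median 2.09; 6 adjusted over the list alone), such as the vesicular glutamate transporter Slc17a6 (1.92 ± 0.56) and Calb2 (2.39 ± 0.71), with scores of 3.14, 1.44 and -0.02 in the 3 mutants and 0.76 in the highest wild type. Genes of cholesterol synthesis were higher in 18 of 21 (8 adjusted over the list alone), such as Stard4 (0.53 ± 0.10), and astrocyte markers in 11 of 12 (3 adjusted over the list alone), such as Gjb6 (0.60 ± 0.10). Markers of the hippocampal CA fields were lower in 8 of 9, postsynaptic density genes in 29 of 34, such as the NMDA receptor subunit Grin1 (-0.31 ± 0.09), and myelin genes in 12 of 12, such as Opalin (-0.46 ± 0.12). With an estimated correlation the adjusted p was 0.273 for cholesterol synthesis and astrocytes and 0.477 for the other four. Of the further lists that passed camera, endothelial (12 of 12), mural and meningeal (16 of 16), choroid plexus (14 of 14) and erythrocyte genes (5 of 5), the unfolded protein response (14 of 15) and oxidative phosphorylation (51 of 74) were higher. Synaptic vesicle genes (19 of 25), immediate-early genes (15 of 18) and markers of excitatory (10 of 12) and inhibitory neurons (10 of 14) and of the dentate gyrus (7 of 8) were lower. None of these kept its call with an estimated correlation (adjusted p of at least 0.477). Outside the interval 0 of 15095 genes changed in edgeR, with 1011 at an unadjusted p under 0.05 and 13 called by DESeq2. An exact permutation test of 3 against 3 libraries could not go below 0.1.

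Between the 15q13 doses, 4 genes differed in effect in cortex: Gm20457 inside the interval, Rnaseh2c (difference -0.49 ± 0.09, homozygous minus hemizygous), Gm13375 (-0.63 ± 0.12) and the glutathione transferase Gsto1 (-0.44 ± 0.09). In hippocampus 3 differed, Gm20457, Gm44718 and Gm32633, all inside the interval. Between hemizygous cortex and hippocampus 4 differed: Dpp10, a potassium channel subunit (difference -0.86 ± 0.13, cortex minus hippocampus), Etnppl (-1.68 ± 0.30), Cacng8 (0.56 ± 0.10) and Ptpn4 (-0.88 ± 0.16). These genes were named after their values were seen, and doses and tissues came from different studies; hemizygotes were all male, while 6 of 8 homozygotes in each tissue were female, so that sex too goes with dose.

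Across models, the effects in cortex of the 15q13 and 22q11 hemizygous deletions, sequenced in the same study, differed for 779 genes, 211 higher for 15q13 and 568 higher for 22q11. Another split of the same libraries gave 986, and fewer genes differed with no filter on low counts. The nuclear-retained mean differed between mutants and wild types by 0.51 in 22q11 cortex and by -0.07 in 15q13 cortex. How many of the 779 follow that mean was not tested. Emc10 was 0.03 higher in 15q13 and rose by 0.51 in 22q11, a difference of -0.47 ± 0.04 (adjusted p = 4.5e-11), and C130071C03Rik differed by -0.57 ± 0.08. In hippocampus, 15 genes differed between the 1q21 and 22q11 deletions, 5 higher for 1q21 and 10 for 22q11, among them C130071C03Rik (-0.59 ± 0.07), Mir22hg (-0.62 ± 0.10) and Gm26723 (-2.13 ± 0.35). Over all 28 pairs of comparisons, 0 correlations of fold changes across genes passed after adjustment (smallest adjusted p 0.554 for Spearman rho and 0.444 for Pearson r, over reassigned genotypes). The reassignments were too few for a pair on its own to pass adjustment over 28 pairs, however strong its correlation. The count of 0 therefore does not show that effects are uncorrelated. Cortex and hippocampus of 22q11 mice had Spearman rho -0.28 and Pearson r -0.35 across 14016 genes (p = 0.0792 and 0.0198 before adjustment); genes are not independent replicates.

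**Figure D5:**
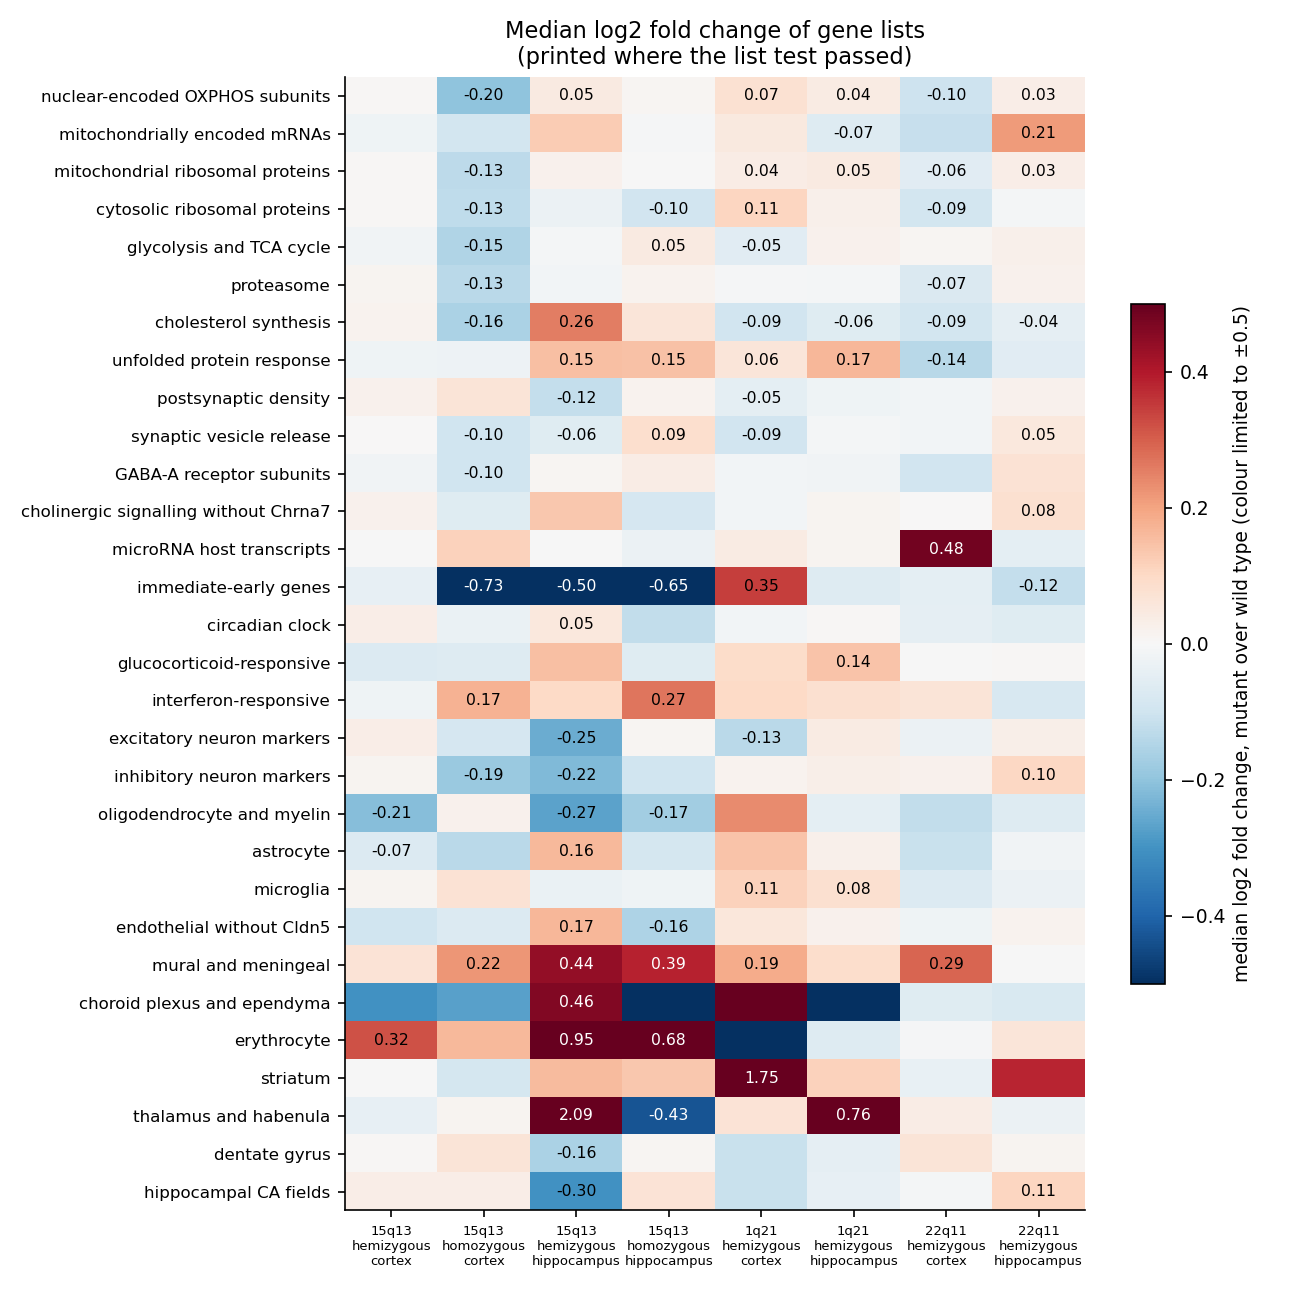
Median log2 fold change, mutant over wild type, of the gene lists that passed the camera test in at least 1 comparison, by comparison; values are printed where that list passed, and the colour scale ends at ±0.5. Of the 82 printed cells, 1 also passed with an estimated correlation, the microRNA host transcripts in 22q11 hemizygous cortex (0.48).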

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

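The tests of the Dgcr8 dose, of variants carried along with the deletion and of the dose of the 15q13 genes were chosen only after the result was seen, as were the list of nuclear-retained transcripts on which the tests of RNA makeup rest, the tests of microRNA hosts with that score as covariate, and the splits without genes inside the intervals, while the other splits and the test of library size were planned. In 22q11 hemizygous cortex 1381 genes outside the deletion changed, 73.2% of them upward, and 1476 differed in effect from hippocampus. Library totals differed little, from 10.81 to 12.39 M in wild-type and from 11.51 to 12.79 M in hemizygous cortex, which leaves library size little room as a cause. With every library thinned to the smallest total, 1338 genes changed. That thinning removed few counts and could hardly have lowered the number, so it decides nothing by itself. RNA makeup that also varies between libraries of 1 genotype stays open: of 1334 called genes, 82.38% had the sign that the same genes follow with the nuclear-retained score across the 15q13 cortex libraries, against 56.5% of genes not called, and the score differed between the genotypes by 0.51 log2 in cortex and by -0.26 in hippocampus; whether the preparation or the deletion moved it was not tested. A lower dose of Dgcr8, which may slow the cleavage of primary microRNAs, also stays open: annotated long non-coding hosts moved above other long non-coding genes by 0.47 log2 in cortex (24 of 42 rose; permutation p = 2e-05, with 1 of 100000 draws as large) but by 0.0369 in hippocampus (4 of 41 rose; exact permutation p = 0.563), and without the hosts already named by 0.30 (12 of 28 rose) and -0.02 (1 of 27 rose; p = 0.769), which is too near 0 to decide. With the score as covariate, 11 of 13 genes called in cortex and 10 of 12 in hippocampus were microRNA hosts or microRNAs, against 5.17% and 5.04% of genes tested (Fisher's exact p = 4.7e-13 and 6.0e-12), where without it 119 of 1381 and 6 of 15 were; all 13 in cortex but 6 of the 12 in hippocampus were called in both fits, and there the hosts C78859, Ftx and Spaca6 had folds below 0 without it (-0.14, -0.15 and -0.00681), so the hippocampal share rests in part on the covariate.

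In 15q13 homozygotes, 8 genes outside the interval changed in both tissues. Variants carried along on the chromosome of the deletion are argued against as the source of all of them, since 12.5% of the 8, namely Cyp2e1, lie on chromosome 7, where 8.26% of all genes lie. The dose of the deleted genes could not be decided: of the 4 shared genes tested in hemizygous cortex, 75% had the same sign, and in hemizygous hippocampus 4 of 4 did, with none past the threshold. Fchsd1 was 0.35 ± 0.08 in hemizygous cortex (adjusted p = 0.608) and rose by 0.67 in homozygous cortex. Strain background elsewhere in the genome was not tested and stays open.

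In 15q13 homozygous cortex, lists of energy metabolism and protein turnover passed camera downward, but 0 of the 12 called lists kept their call with an estimated correlation (adjusted p = 0.430 for oxidative phosphorylation). The nuclear-retained share of RNA as their cause could not be decided. With that score as covariate, 10 of the 12 called lists stayed past the threshold in the same direction. Among them was oxidative phosphorylation (camera adjusted p = 2.0e-23 with the preset correlation). Synaptic vesicle genes and GABA-A receptor subunits lost their calls (camera adjusted p = 0.120 and 0.551). Splits of the libraries at random often pass the same test, so staying past it cannot settle a cause. Chance stays open for the number of lists, because 58 of 100 splits of the same libraries gave as many. An effect of the homozygous deletion itself also stays open.

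Other splits of the same libraries bear on every count. The genes changed in 22q11 hemizygous cortex (1381) were matched by 1 of 100 splits, the real one, with 2 in the highest other split, and those in 22q11 hippocampus (15) by 1 of 100, with 0 in the highest other. In 15q13 homozygous hippocampus the real split gave 50 and the highest other 6 (1 of 100). Chance is argued against for these 3. It is not excluded for 15q13 homozygous cortex (46 genes) and 1q21 hippocampus (14 genes), where 3 of 100 splits each were as large. Single other splits there gave 1784 and 109, which points to a structure of the samples other than genotype. These shares of splits are not adjusted for the number of counts tested. Without the genes inside the intervals, whose calls the deletion fixes, 40 and 45 genes changed in homozygous cortex and hippocampus (3 and 1 of 100 splits) and 14 in 22q11 hippocampus (1 of 100). For the edgeR counts of 0 in 15q13 hemizygous cortex (454 genes at an unadjusted p under 0.05, 2 by DESeq2) and 1q21 cortex (739 and 1), all 100 splits are as large by construction, which says nothing on chance; the highest other counts were 4 and 1030, the latter pointing to a structure of the samples, which was not traced to libraries.

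For the number of lists, chance cannot be excluded in 7 comparisons. As many were called in 93 of 100 splits for 15q13 hemizygous cortex (3 lists, highest other 16), 58 for homozygous cortex (12, 20), 75 for homozygous hippocampus (11, 20), 27 for 1q21 cortex (13, 19), 78 for 1q21 hippocampus (8, 18), 70 for 22q11 cortex (8, 23) and 78 for 22q11 hippocampus (9, 20). In 15q13 hemizygous hippocampus, the 10 splits of 3 against 3 are too few for a share under 0.05: the real split gave 0 genes by edgeR (1011 at an unadjusted p under 0.05, 13 by DESeq2) and 18 lists and the highest other 445 genes and 18 lists, with 10 and 2 splits as large.

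Effects that differed between groups were found in 6 of 8 interaction tests. Between 22q11 tissues 1476 genes differed (1 of 100 splits, highest other 1), in cortex between 15q13 and 22q11 hemizygotes 779 (2 of 100, highest other 986), and in hippocampus between 1q21 and 22q11 hemizygotes 15 (1 of 100, highest other 6). Between 15q13 doses 4 differed in cortex (4 of 100, highest other 1327) and 3 in hippocampus (3 of 100, highest other 16). All 3 of the latter and 1 of the former lie inside the interval, so that in hippocampus the deletion itself fixes the outcome; the 3 others in cortex were matched by 4 of 100 splits. Chance is argued against for the 22q11 tissues and for 1q21 against 22q11 in hippocampus. It is not excluded for 15q13 against 22q11 in cortex or for the 15q13 dose in cortex, where other splits gave more genes than the real one. For the dose in hippocampus the splits say nothing beyond the deletion. Chance is also not excluded for the 4 genes that differed between 15q13 hemizygous tissues (16 of 100, highest other 865). By edgeR 0 differed between 1q21 tissues (1445 at an unadjusted p under 0.05, 30 by DESeq2) and between 15q13 homozygous tissues (1369 and 0); all 100 splits gave as many by construction, which says nothing on chance, with 157 and 133 in the highest other. Other splits that called several times the real count point to a structure of the samples in 5 of these tests. The tissues of each hemizygous model and the 15q13 doses were in different studies, so that tissue or dose and study cannot be told apart, and hemizygotes were all male where 6 of 8 homozygotes were female. Among deleted genes, Trmt2a (difference 0.41) and Arvcf (0.25) were lowered less in 22q11 cortex than in hippocampus.

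In 127 sets of values, each 1 measure over a group of 4 to 10 libraries, 18 values stood far from the rest. For a single set, chance gives about 1 in 20. The sets share libraries, so they are not independent. In 15q13 homozygous cortex, library 225 had a deleted-gene median of -7.999 where the next was -9.55, library 220 a total of 112.5 M, and library 228 a cholesterol synthesis score of 0.11. Most homozygous cortex libraries had the same deleted-gene median of -9.64, the floor that the prior count sets at 0 counts. A few reads are enough to stand apart from that floor, so the share expected by chance does not apply to that set. In homozygous hippocampus, library 241 scored 0.996 for interferon-responsive genes, and wild-type libraries 248 and 236 scored -0.29 for these and 1.33 for thalamus. In 1q21 hippocampus, hemizygous library 95 had a total of 17.96 M and a glucocorticoid-responsive score of 0.86. In 22q11 cortex, wild-type library 181 scored 0.12 for oxidative phosphorylation, and hemizygous libraries 183 and 188 scored 0.21 for cytosolic ribosomal proteins and -0.21 for the proteasome. In 22q11 hippocampus, wild-type library 113 had a deleted-gene median of 0.255, scored 0.43 for oxidative phosphorylation and 0.32 for mitochondrial ribosomal proteins, and wild-type library 114 scored 0.36 for cholinergic signalling. Hemizygous library 121 had a total of 23.93 M, library 124 scored 0.17 for mitochondrial ribosomal proteins and library 123 scored 0.40 for cholinergic signalling.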

How the results depend on the processing

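The covariate of nuclear-retained transcripts, the removal of the interval by coordinates, halved counts and the removal of libraries that stood apart were chosen after seeing the data, and the other alternatives were planned. Across them, 177 counts, medians and other results that answer a comparison were scored as kept and 52 as moved. A count was kept if it stayed within 1.5 times its value or if a count of 0 stayed 0. The median of the deleted genes was kept if it shifted by less than its SD over the mutant libraries. Counts have no direction, so only these medians could reverse, and 0 did. With an estimated correlation between genes, the gene lists past the threshold went to 0 in 7 comparisons and to 1 in 22q11 hemizygous cortex.

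With the DESeq2 Wald test, the genes changed outside the deleted list were 2 in 15q13 hemizygous cortex, 251 in homozygous cortex, 13 in hemizygous hippocampus, 259 in homozygous hippocampus, 1 in 1q21 cortex, 95 in 1q21 hippocampus and 62 in 22q11 hippocampus. All edgeR calls of the homozygous and hippocampal comparisons that had any were among them (46, 50, 14 and 15). The same test gave 30 genes with a different effect between 1q21 tissues, 12 between the 15q13 doses in hippocampus and 86 between 15q13 hemizygous tissues.

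With sample quality weights, 398 genes changed in 15q13 homozygous cortex, 385 in homozygous hippocampus, 46 in 1q21 hippocampus and 60 in 22q11 hippocampus, and 8 lists passed in 15q13 hemizygous cortex. With 2 surrogate variables, 1 gene changed in 15q13 hemizygous cortex, 211 in homozygous cortex, 6 in 1q21 hippocampus and 2481 in 22q11 cortex; 6 lists passed in 15q13 hemizygous cortex, 14 in 22q11 cortex and 14 in 22q11 hippocampus. The joint fit of both models gave 1 gene in 15q13 hemizygous cortex and 46 in 22q11 hippocampus. The cause of these shifts was not tested.

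With no filter on low counts, 7 genes changed in 15q13 hemizygous hippocampus and 9 in 22q11 hippocampus, where 14 lists passed, and the effects differed for 7 genes between the 15q13 doses in cortex, for 16 between 15q13 hemizygous tissues and for 485 between 15q13 and 22q11 cortex. The median of the deleted genes, then including Trpm1, was -8.92 in 15q13 homozygous cortex and -9.87 in hippocampus. Without the sex term, 26 genes changed in 15q13 homozygous cortex; among females alone, with fewer samples, 19 changed and the median of the deleted genes was -11.65.

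With the nuclear-retained score as covariate, 103 genes changed in 15q13 homozygous cortex, 6 in 1q21 hippocampus and 13 in 22q11 cortex, and 7 lists passed in 1q21 cortex, 4 in 22q11 cortex and 15 in 22q11 hippocampus. Leaving out libraries that stood apart, most of them of 1 genotype, gave 8 lists in 1q21 cortex, 2 genes in 1q21 hippocampus and 27 genes in 22q11 hippocampus. In 22q11 cortex the library left out was wild-type library 173, which scored 1.41 for choroid plexus against at most 1.02 in the other 19. Leaving out each library in turn left 0 genes changed in 15q13 hemizygous hippocampus and in 1q21 cortex, and the median of the deleted genes ran from -1.18 to -0.96 and from -1.01 to -0.97. Of the values of named genes under the alternatives, 3465 kept their side of the threshold, 107 came to pass and 129 no longer did. The 56 of pairs of comparisons all kept theirs, but the few reassignments behind them left little room to pass. DESeq2 size factors, halved counts and removal of the interval by coordinates moved none of the counts or medians of mutant against wild type for which they were run beyond 1.5 times; without genes inside the intervals, the 3 genes that differed between the 15q13 doses in hippocampus went to 0. In 15q13 hemizygous hippocampus, 0% of the changes of the smallest simulated fold were found, so small changes were not detectable there.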

Other observations

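The overlap counts in this part were chosen after the calls were seen, and the list tests were planned. Feedback targets of Wnt signalling, the pathway in which the deleted gene Bcl9 acts, showed no shared direction in 1q21 mice: 0 of 11 changed in cortex or hippocampus by edgeR, with medians of -0.01 and 0.03 (camera adjusted p = 0.487 and 0.974). Cholinergic signalling genes other than Chrna7 were lower in 14 of 19 in 15q13 homozygous cortex, where 0 changed over all genes and 1 rose and 2 fell adjusted over the list alone, and lower in 11 of 19 in homozygous hippocampus; neither list passed (camera adjusted p = 0.136 and 0.796). Markers of cortical layers did not pass in cortex of any model: 8 of 11 were lower in 15q13 hemizygotes, 8 of 12 in 15q13 homozygotes and 7 of 11 in 22q11, and 8 of 12 were higher in 1q21 (camera adjusted p = 0.239, 0.802, 0.955 and 0.730). Markers of oligodendrocyte precursors had 0 of 8 members past the threshold in any comparison, and their smallest camera adjusted p was 0.0641, in 1q21 hemizygous cortex, where 7 of 8 were higher.

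Microglial markers were higher in 10 of 12 in 1q21 hemizygous hippocampus, such as the complement gene C1qc (0.23 ± 0.09), with 0 past the threshold and 1 adjusted over the list alone (camera adjusted p = 0.00598; adjusted p = 0.633 with an estimated correlation). Glucocorticoid-responsive genes were also higher in 10 of 12 there, such as Hif3a (0.64 ± 0.25), with 0 past either threshold (camera adjusted p = 0.0318; adjusted p = 0.633 with an estimated correlation), and hemizygous library 95 scored 0.86 for them. Without the hemizygous libraries 95, 96 and 99, which scored higher than the others for thalamus, an alternative chosen after seeing the data, the adjusted p was 0.0352 for microglial and 0.234 for glucocorticoid-responsive genes.

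Genes of the circadian clock were higher in 10 of 15 in 15q13 hemizygous hippocampus, where Hlf was 0.48 ± 0.09 higher and was the 1 member to pass adjusted over the list alone (camera adjusted p = 0.0331; adjusted p = 0.477 with an estimated correlation). Between 15q13 homozygous cortex and 22q11 hemizygous cortex, 2 rises were shared, Asap3 and the interferon-inducible Ifi203, against 0.555 if the calls were independent, and 2 falls, Gsto1 and the spermidine synthase Srm, against 0.591. Immediate-early genes had medians of -0.73, -0.65 and -0.50 in 15q13 homozygous cortex, homozygous hippocampus and hemizygous hippocampus, of -0.12 in 22q11 hemizygous hippocampus, and of 0.35 in 1q21 hemizygous cortex; whether these differ between the models was not tested.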
